A study of Arabidopsis thaliana with 4 samples.

How the data were processed

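Total RNA of Arabidopsis thaliana was measured on 1-colour Affymetrix arrays. Each sample was a mix of equal parts of rosette leaves, stem leaves and flowers, per the labels. The labels name 3 independent groups of plants carrying an inverted repeat against myosin XI-K, which triggers RNA interference (RNAi), and 1 control group that expresses the bacterial reporter gene GUS. There is 1 array per group of plants. Biotin-labelled cRNA was stained with phycoerythrin, per the labels' protocols.

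The deposited values are probe set intensity on a linear scale, made with GCOS and MAS5 per the submitters' processing notes; their versions are not given in the sources used here. The mean of each column after trimming 2% from both ends lay at 500.05 or 500.06, so the arrays had been brought to 1 level before deposit and were not scaled again. Medians were 156.1 for the control column, 156.1 for RNAi group 1, 170.25 for RNAi group 2 and 159.7 for RNAi group 3. Between 24.9% and 27.6% of the signals of an array lay under 32. Detection calls were not used here. The number of arrays limits the precision.

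The columns of the GUS control and of RNAi group 1 held identical values in all 22810 rows. Other pairs of arrays shared 56 to 67 rows. The pair was counted as 1 sample, called the shared array. The labels do not tell which of the 2 plant groups it measured. The planned fit of all 4 columns was therefore replaced by a fit of RNAi groups 2 and 3 (n = 2) against the shared array (n = 1). This change was made after the files were seen, and the planned fit is given among the alternatives. If the shared array is the control, differences part silenced from control plants. If it is RNAi group 1, they part silenced groups from each other.

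Of the 22810 probe sets, 64 control probe sets were left out. Genes were named through the platform annotation of the array, updated through the gene identifiers of the TAIR10.1 reference table, from which no coordinates were taken. That annotation lists 13513 probe sets with 1 gene, of which 13436 matched the reference table, and 503 with several genes, which were not named. The other 8730 probe sets are unnamed here. The named probe sets do not include one for myosin XI-K, so the level of the silenced gene is not reported here.

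Signals were put on the log2 scale. Probe sets with a mean log2 signal above the 30th percentile (5.307) were kept, which left 15922, with 8669 of them named by 1 gene. Differences were tested with limma's lmFit and eBayes with an intensity trend, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The spread came from 2 arrays, with 1 residual degree of freedom and 7.45 prior degrees of freedom, and the shared array was assumed to vary like the RNAi arrays. The labels call the plant groups independent; each p-value measures the spread between 2 arrays. List members under the filter took their SE and p from a separate fit over all probe sets. R 4.3.3 and limma 3.58.1 were used.

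The procedure was tested on simulated data for this comparison, with 200 of 15922 probe sets changed. It recovered 0% of 2-fold, 6% of 4-fold, 70.5% of 16-fold and 91% of 64-fold changes, with 0, 13, 8 and 21 false calls. In 100 simulated draws with no change, 27 gave at least 1 call, 15 gave at least the 5 calls seen in the data, and the highest gave 72. The draws started from the kept probe sets and did not repeat the filter.

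Gene lists were fixed before the data were examined: myosins, actin cytoskeleton, tubulins, RNA silencing, floral organ identity, anther tapetum, pollen, seed storage, root, photosynthesis, senescence, salicylate defence, jasmonate, heat shock, cold and ABA, touch and rapid stress, circadian clock, cell wall and expansion, trichome patterning, cell division, flavonoid and anthocyanin, and reference genes. Lists with at least 5 kept members were tested with limma's camera (preset correlation 0.01, with an estimated correlation beside it). With an estimated correlation, camera is limited to the residual degrees of freedom, 1 here, so hardly any list could pass it. Further lists were added after the largest differences had been seen: mature pollen, young flower and meiosis, tapetum, seed and embryo, nuclear photosynthesis, plastid-encoded and mitochondrion-encoded genes. List medians were set against 10000 random lists matched on mean signal, with 95% bootstrap intervals over members.

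The named genes follow a rule written before the data were examined. It takes all myosins, then up to 12 genes with the largest rise and 12 with the largest fall past the test. Where fewer passed, it fills up with the largest differences among genes at least 2-fold from the shared array in both RNAi arrays, given as values that did not pass. From each list it takes the members past the test or, with fewer than 2, the 2 with the largest difference. A gene with several probe sets is represented by the one with the highest mean signal.

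Alternatives were quantile normalisation, centring on medians, a floor of 32, an offset of 16, no filter, a filter at the 50th percentile, eBayes without the trend or robust, arrays left out in turn, camera with an estimated correlation or with ranks, and adjustment over the myosin list alone. The same adjustment over other lists was not planned, and it takes no account of the number of lists. Added after the data were seen were the planned 4-column fit, an estimated correlation without a filter, and the floor of 32 together with either scaling. Calls with RNAi group 2 as the lone array were set against 100 simulated draws with no change.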

Results

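Expression was measured in Arabidopsis plants in which myosin XI-K, an actin-based motor, was targeted by RNAi. The deposited values cover 3 RNAi groups and 1 GUS control, each with 1 array. The GUS control and RNAi group 1 held identical values in all 22810 rows and were counted as 1 sample, the shared array. RNAi groups 2 and 3 (n = 2) were compared with it (n = 1). Because the shared array carries the labels of both a control and a silenced group, no difference given here is assigned to silencing. The kept probe sets at least 2-fold apart numbered 1600 between the shared array and RNAi group 2, 1236 between it and RNAi group 3, and 2683 between RNAi groups 2 and 3.

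The series asked how the 17 myosin RNAs of the plant compare between silenced and control plants. XIC and XIE, whose products are known to act in pollen tubes, had the largest differences among the 6 myosins named here. XIC had a signal of 18.6 on the shared array, 77.6 in RNAi group 2 and 58.2 in RNAi group 3, a log2 difference of 1.85 (SE 0.75; limma adjusted p = 0.9999), or 1.07 with signals under 32 set to 32. XIE had 4.5, 57.0 and 45.0, a log2 difference of 3.49 (SE 0.89) that rests on a dim signal under the filter and was 0.66 with that floor. XI-I had 176.6, 227.9 and 233.1, with a log2 difference of 0.38 (SE 0.51).

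The other named myosins lay closer to the shared array. XIH differed by -0.01 (SE 0.61), XIJ by 0.20 (SE 0.85) and the class VIII gene VIIIB by 0.00 (SE 0.83) on the log2 scale. XIJ and VIIIB lay below the shared array in one RNAi group and above it in the other. In limma, 0 of the 4 myosins past the filter passed over all probe sets. XIE and XIJ were under the filter and had no such adjusted p. Adjusted over the list alone, 0 of the 6 passed, and XIE had the smallest limma adjusted p, 0.0718. With 4 members past the filter the list was too short for a set test; without the filter, when dim members such as XIE enter, limma's camera called the list higher (adjusted p = 0.0288), with 3 of 6 members higher in both RNAi groups and the call lost with an estimated correlation (adjusted p = 0.321). With an estimated correlation camera has 1 degree of freedom here, so that loss tells little. No probe set is named here for myosin XI-K or the remaining myosins, so no value is given for them and the labels were not checked against the silenced gene.

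**Figure D1:**
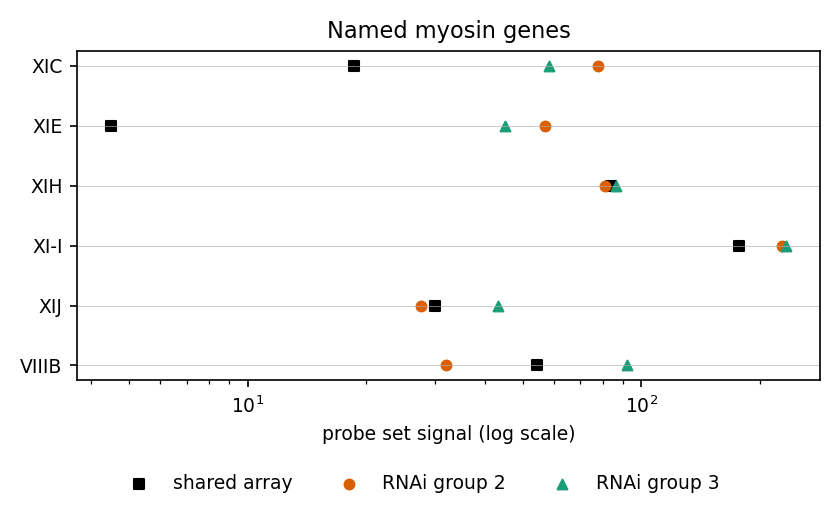
Probe set signal (log scale) of the 6 named myosin genes on the shared array, RNAi group 2 and RNAi group 3, 1 point per array. XIC lies at 18.6 on the shared array and at 77.6 and 58.2 in the RNAi groups, XIE at 4.5, 57.0 and 45.0, and XIH between 80.9 and 86.1; none passed the test.

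Across all genes, AT5G07430, AT3G07820 and AT5G45880 rose from near-background signals on the shared array to clear signals in both RNAi groups. AT3G07820 encodes a polygalacturonase and AT5G07430 a pectinesterase, enzymes that act on cell wall pectin, and AT5G45880 a protein of the pollen Ole e family. AT3G07820 had 3.0 on the shared array and 709.5 and 296.2 in RNAi groups 2 and 3, a log2 difference of 7.26 (SE 0.71). AT5G07430 had 1.9, 496.8 and 192.1 (7.35, SE 0.80), and AT5G45880 had 11.3, 949.6 and 391.6 (5.75, SE 0.65). All 3 had an adjusted p of 0.0478 in limma and were higher in 2 of 2 RNAi arrays. With signals under 32 set to 32, their differences were 9.65-fold for AT5G07430, 14.3-fold for AT3G07820 and 19.1-fold for AT5G45880, and none passed.

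Of 15922 probe sets, 5 passed as higher and 0 as lower in limma. The other 2 higher probe sets are unnamed here and had log2 differences of 5.87 and 6.87, from near-background signals of 6.2 and 2.4 on the shared array, or 3.51 and 3.13 with the floor of 32. At an unadjusted p under 0.05, 147 were higher and 48 lower, and the smallest adjusted p of a lower probe set was 0.429. Simulated data with no change gave at least 5 calls in 15 of 100 draws. The simulation did not repeat the filter and gave all arrays the same spread for a probe set. It therefore gives no chance rate for calls that are near background on the shared array alone. Quantile normalisation, an offset of 16, no filter and robust eBayes also left 0 higher probe sets. The planned 4-column fit gave 0 too. It counts the shared array in both groups, which widens the spread within the RNAi group, so it could hardly keep such calls.

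Further genes with large differences did not pass, and most were near background on the shared array. GILT, named for a thiol reductase family, had 5.3 on the shared array, 1006.1 in RNAi group 2 and 161.8 in RNAi group 3 (log2 difference 6.25, SE 0.98, limma adjusted p = 0.125). PC1, a pollen calcium-binding protein, had 5.2, 209.4 and 63.6 (4.47, SE 0.91). AT1G29140, another gene of the pollen Ole e family, had 4.6, 254.0 and 140.2 (5.36, SE 0.74). The pectate lyase gene AT3G01270 had 31.6, 616.4 and 328.2 (3.83, SE 0.58), and AT3G28750 had 35.2, 933.7 and 506.4 (4.29, SE 0.57). The log2 differences of AT5G61720, AT3G01240, AT5G26700 and AT4G13230 were 5.75, 5.42, 5.33 and 4.44. With the floor of 32 the differences were smaller for the dim genes: 3.66 for GILT, 1.85 for PC1, 2.56 for AT1G29140, 2.82 for AT5G61720, 2.72 for AT3G01240, 2.22 for AT5G26700 and 2.48 for AT4G13230.

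The genes with the largest negative differences also did not pass. AT5G17540 had 891.3 on the shared array, 72.5 in RNAi group 2 and 167.6 in RNAi group 3 (log2 difference -3.02, SE 0.62, limma adjusted p = 0.429). The small heat shock gene AT4G21870 had 2040.5, 448.2 and 310.2 (-2.45, SE 0.53). BHLH101, a transcription factor of the iron deficiency response, had 239.8, 96.7 and 36.4 (-2.02, SE 0.73). JMT, which makes methyl jasmonate, had 3156.0, 678.6 and 1221.3 (-1.79, SE 0.56). AT3G06070, AT5G38130, AT1G72920, BAT1, AT1G43910, AT1G12030, AT5G55570 and AT2G22200 had log2 differences of -2.31, -2.14, -2.08, -1.97, -1.88, -1.83, -1.77 and -1.76.

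**Figure D2:**
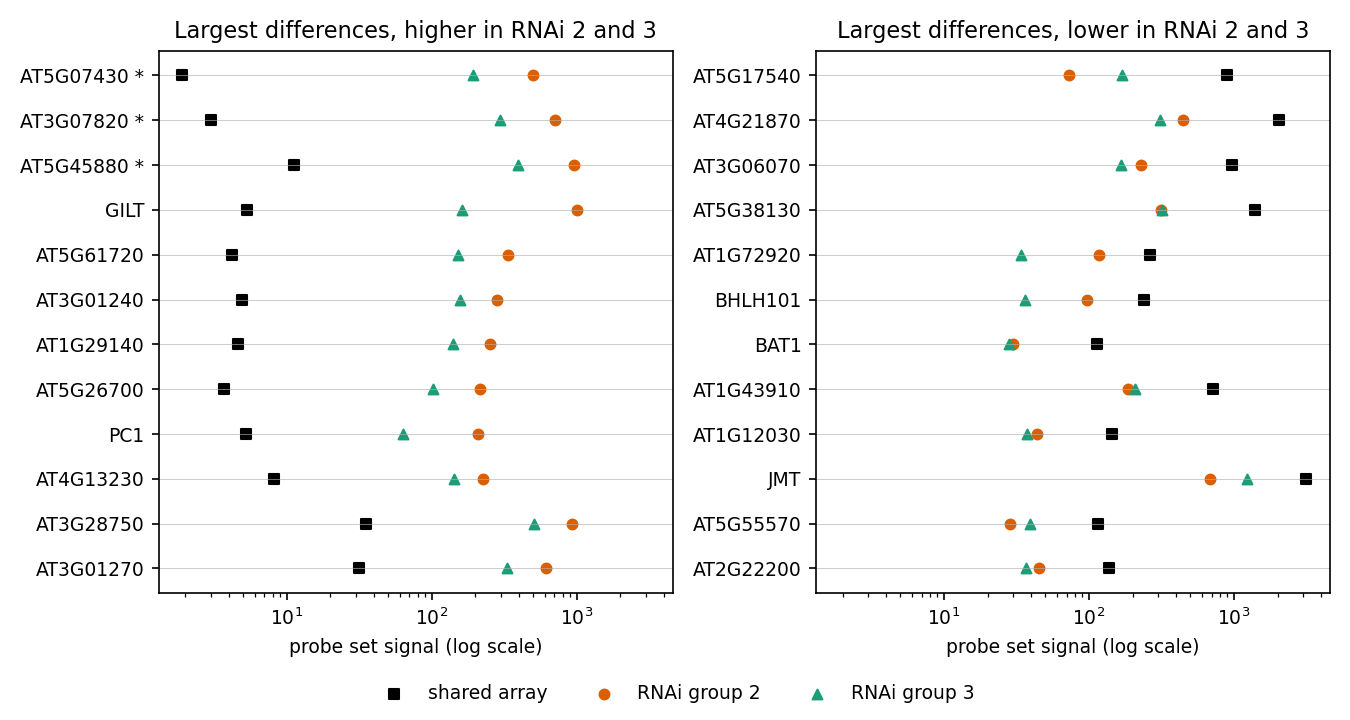
Probe set signal (log scale) of the named genes with the largest differences, 1 point per array, with a star for the 3 genes past the test. The left panel holds 12 genes higher in both RNAi groups, from AT5G07430 (1.9 on the shared array) to AT3G01270 (31.6), and the right panel 12 genes lower in both, none of which passed.

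At least 2-fold differences in the same direction in both RNAi groups were found for 202 higher and 58 lower probe sets. Both comparisons use the same lone array. Simulated data with no change, drawn with the spread between RNAi groups 2 and 3, gave 415 to 510 higher and 414 to 501 lower. Both observed counts lie below these ranges, so the simulated spread is too wide to tell whether the total is above chance. The excess of higher probe sets was narrower with quantile normalisation (157 against 74), median centring (173 against 79), the floor of 32 (147 against 58) and the floor with median centring (123 against 79). At 8-fold, a size chosen after the values were seen, 34 were higher and 0 lower, against 0 to 7 and 2 to 11 in the simulation. With the floor of 32, 12 were higher and 0 lower. The filter takes the mean over the arrays, so it more readily keeps probe sets dim on the shared array alone than in both RNAi groups. The simulation did not repeat this filter, so it cannot calibrate the excess of higher probe sets. Without a filter, 1258 were 2-fold higher and 649 lower. Of the 202, 73.3% had a higher signal in RNAi group 2 than in RNAi group 3. Taken singly against the shared array, RNAi group 2 had 1002 probe sets 2-fold higher and 598 lower, and RNAi group 3 had 607 higher and 629 lower. With RNAi group 2 as the lone array, 629 were higher and 385 lower in it; with RNAi group 3, 256 were higher and 399 lower.

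**Figure D3:**
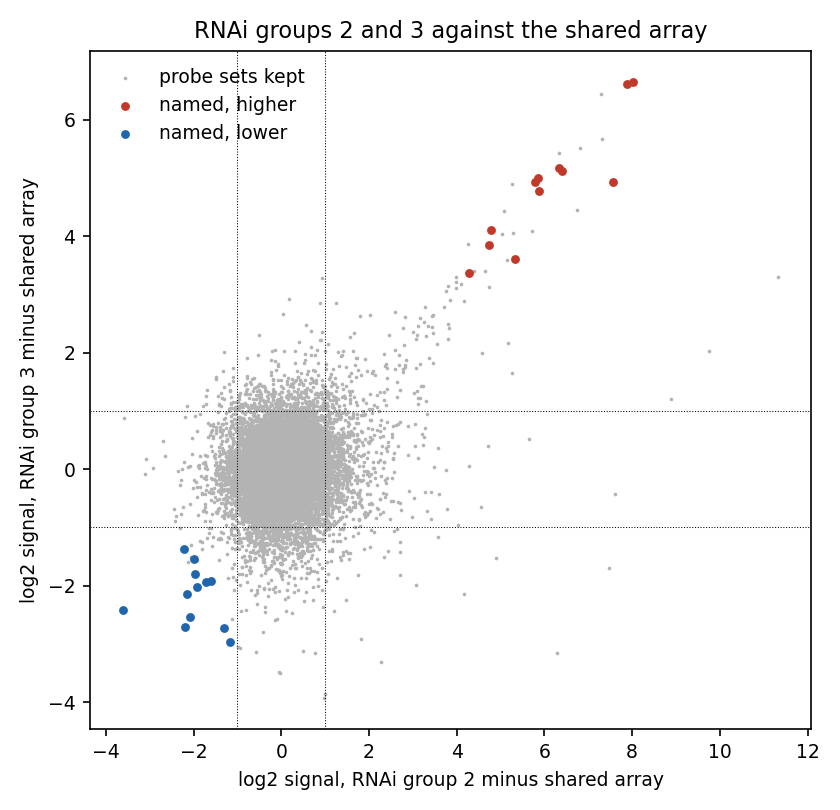
Log2 signal difference from the shared array in RNAi group 2 (horizontal) and RNAi group 3 (vertical), 1 grey point per kept probe set, with the named genes in red (higher) and blue (lower) and dotted lines at 2-fold. The 34 probe sets at least 8-fold higher in both form a trail to the upper right, with none 8-fold lower in both.

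Among the gene lists fixed beforehand, tubulins were the only one with enough kept members for a set test. The list holds 15 tubulins, of which 7 had a named probe set. These 7 had a median log2 difference of 0.41, at percentile 99.72 of matched random lists, and 4 of them were higher in both RNAi groups. Because both groups are set against 1 array, 33.3% of probe sets are higher in both with no change in simulated data, and 30.2% of all kept probe sets were. TUB1 had 120.5 on the shared array and 192.8 and 626.2 in RNAi groups 2 and 3 (log2 difference 1.53, SE 0.72), and TUB5 had 892.6, 1953.3 and 1324.2 (0.85, SE 0.53). The list was higher by limma's camera (adjusted p = 0.00642), and the call was lost with an estimated correlation (adjusted p = 0.218 with an estimated correlation) and without a filter on dim probe sets (camera adjusted p = 0.0786). The estimated correlation was -0.143, below the preset 0.01, and that version has 1 degree of freedom, so hardly any list could pass it. No tubulin passed on its own, over all probe sets or adjusted over the list alone.

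The defence and growth lists had few named members, and 0 passed over all probe sets in limma. The plant defensins PDF1.2 and PDF1.2b, markers of jasmonate and ethylene signalling, had 158.8 and 95.1 on the shared array. PDF1.2 had 370.4 and 437.4 in RNAi groups 2 and 3 (log2 difference 1.34, SE 0.51) and PDF1.2b had 192.9 and 331.3 (1.41, SE 0.57). Adjusted over the list alone, a step not planned for this list and not corrected for the number of lists, both had a limma adjusted p = 0.0366. The expansin EXPA8 had 86.4, 774.1 and 201.1 (2.19, SE 0.77), and EXPA4 differed by 0.25. TRY, a repressor of leaf hair formation, had 493.6, 184.9 and 216.3 (-1.30, SE 0.51). In the same way EXPA8 had a limma adjusted p = 0.0407 over its list alone. TRY is the only named member of its list, so no adjustment over the list applies to it.

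The heat shock, cold and touch lists had few named members here, and 0 passed in limma. The small heat shock genes ATHSP22.0 and AT1G53540 had 13069 and 18839.1 on the shared array, with log2 differences of 0.14 (SE 0.53) and 0.12 (SE 0.48). COR15A and COR47, cold-induced protectants, had 8821 and 12048.2, with differences of 0.54 and 0.50. COR15A was brightest in RNAi group 2, at 22368.1, against 7359.0 in RNAi group 3. The touch and stress genes CML38 and STZ had 3054.3 and 5432.1, with differences of -0.31 and -0.15. In the senescence list WRKY53 differed by 1.09 (SE 0.64) and SAG101 by -0.72 (SE 0.63), and the clock gene GI by 0.69 (SE 0.55).

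In the tapetum list, the cell layer that feeds pollen, AT5G07230 and AMS differed by -0.27 and -0.24. The photosynthesis genes LHCB4.1 and RCA differed by -0.24 and 0.00. In the cytoskeleton list ACT11 differed by -0.18 and AT2G30690 by -0.88, and the pollen list held ACT12 alone, at -0.41. AT2G30690 and ACT12 were under the filter, went opposite ways in the RNAi groups and were positive with the floor of 32 (0.28 and 0.27). In the root list EXPA7 and PYK10 differed by -2.73 and 0.99, both under the filter, and by 0.00 and 0.45 with the floor of 32. AGO7 of RNA silencing differed by 0.38, AUR1 of cell division by 0.16, and DFR and UF3GT of anthocyanin synthesis by 0.43 and 1.64. UF3GT was under the filter, with 11.9, 85.7 and 16.1, and differed by 0.71 with the floor. The reference genes AT4G34270 and AT2G28390 differed by 0.39 and 0.20. The floral organ identity, seed storage and salicylate defence lists had no named probe set here.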

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

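The 4-column fit, the estimated correlation without a filter and the floor combined with a scaling were added after the data were seen, and adjustment over lists alone was planned for the myosins only; the other alternatives were chosen before the data were examined. The count of 5 higher probe sets was 5 with median centring (all 5 shared) and with the 50th percentile filter (1 shared, since that filter removed 4). It was 13 without the intensity trend (5 shared). It was 0 with quantile normalisation, a floor of 32, an offset of 16, no filter and robust eBayes, and the cause was not tested. The 4-column fit also gave 0, but it counts the shared array in both groups and could hardly keep such calls. The adjusted p of AT5G07430, AT3G07820 and AT5G45880 ranged from 0.0355 to 1 in limma. No lower probe set and no myosin passed under any setting run. The tubulin call (1 list) became 0 with the estimated correlation, with the filter and without it. That setting rests on 1 residual degree of freedom, so hardly any list could pass it. Without a filter tubulins did not pass (camera adjusted p = 0.0786) and the 6 named myosins did (camera adjusted p = 0.0288). Tubulins passed in the other settings run, with camera adjusted p from 0.0011 to 0.0065.

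The 260 probe sets at least 2-fold in both RNAi groups (202 higher, 58 lower) became 172 with the offset (130 higher), 1907 without a filter (1258 higher, 649 lower) and 92 with the 50th percentile filter (57 higher, 35 lower). The excess of higher probe sets was narrower with quantile normalisation (157 against 74), median centring (173 against 79) and the floor alone (147 against 58), and with the floor added to either scaling (118 against 74 and 123 against 79). Leaving out RNAi groups in turn gave 260 to 1600 in all, 202 to 1002 higher and 58 to 629 lower; with only 1 array counted it was 607 against 629 without group 2 and 1002 against 598 without group 3. Leaving out RNAi group 1 changes nothing, because it is the shared array. Without group 2 or 3 no residual degrees of freedom remain, so no test was run; 23 of those 140 gene values changed sign. In the other settings sign changed for XIJ (-0.022) and EXPA18 (-0.14) with quantile normalisation, TUB7 with median centring (-0.035), AT2G30690 (0.28) and ACT12 (0.27) with the floor and VIIIB with the offset (0.034), and 2 values became 0; none was past the test. Of 535 gene values with an adjusted p there, 16 lost and 5 gained the call, and 512 kept sign and side of the threshold. The alternatives for myosin XI-K itself were not run, because no probe set is named for it here. No paired analysis was possible because the control carries no group number. Signals under 32, which make up 24.9% to 27.6% of an array, limit the folds of the genes that are dim on the shared array.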

Other observations

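The tests of myosin silencing and of the identical columns, the floor combined with centring and the simulation for RNAi group 2 were chosen only after the results were seen; the gene lists used here were chosen after the largest differences were seen and before their own values were. Photosynthesis genes tended lower than on the shared array, unevenly between the RNAi groups, and mitochondrial genes higher, with no member past the test. With no change, simulated data put 33.3% of probe sets higher and 33.2% lower in both. Of all kept probe sets, 30.2% were higher and 23.3% lower in both. The bootstrap intervals resample genes on the same arrays, so they leave out the spread between plant groups. Of 21 nuclear photosynthesis genes, 15 were lower in both, with a median log2 difference of -0.44 (95% bootstrap interval -0.53 to -0.23; -0.57 in RNAi group 2 and -0.17 in RNAi group 3), such as NdhL with 2735.3 on the shared array against 1413.7 and 1602.3. Of 66 plastid-encoded genes, 35 were lower in both (median -0.29, interval -0.36 to -0.22), such as rpoA with 7622.8 against 3944.9 and 4632.7, but 65 were lower in RNAi group 3 (median -0.45) and 35 in RNAi group 2, where 31 were higher (psbA 0.91). Of 14 mitochondrion-encoded genes, 12 were higher in both (median 0.45, interval 0.32 to 0.72), such as cox2 with 109.0 against 408.8 and 211.5. Limma's camera gave adjusted p of 6.96e-05, 2.75e-06 and 6.96e-05, with 0.0033 for the added mature pollen list and 0.0133 for the seed list, both higher, and all of these calls were lost with an estimated correlation (adjusted p = 0.421 with an estimated correlation). That version has 1 degree of freedom here, so hardly any list could pass it and the loss tells little. The pollen list lost its call although its estimated correlation, -0.143, lay below the preset 0.01.

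With RNAi group 2 as the lone array, a choice made after each array had been tried, 13 probe sets were higher and 2 lower in it (limma, smallest adjusted p = 0.00377), against 0 with RNAi group 3. In 100 simulated draws with no change, 1 gave as many for this array and 5 gave as many for the highest of the 3 lone arrays. The spread there comes from the other 2 arrays alone. These draws did not repeat the filter either, so they give no chance rate for calls dim on the other arrays. The cold-regulated gene COR27 had 1724.0 in RNAi group 2 against 144.4 on the shared array and 185.5 in RNAi group 3. AT1G04560 had 993.7 against 19.7 and 28.2, AT4G22470 had 1127.4 against 82.5 and 51.2, and AT3G16670 was lower, at 35.7 against 305.3 and 346.1. These 4 were chosen after their values were seen. A candidate explanation is seed tissue in that sample: the seed list had a median of 1.65 above the other arrays on the log2 scale, at percentile 99.94 of matched lists. PAP85, a seed storage protein, had 463.9 in RNAi group 2 against 17.7 and 23.2, and the late embryo gene M10, under the filter, had 255.7 against 2.6 and 3.0. The oleosin OLEO3 was highest in RNAi group 3 (49.6 on the shared array, 59.9 and 97.1). The dim seed gene IKU2 was lowest in RNAi group 2 (33.5, 3.8 and 9.1), but both RNAi signals lay under 32, so this rank tells little. With 5 kept members the interval was wide, from -0.21 to 4.52, and cold or drought, which also induce LEA genes, stayed untested, with COR15A also brightest in this group (22368.1).

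More probe sets were 2-fold higher than lower in both RNAi groups. Taken singly, it was 1002 against 598 in RNAi group 2 and 607 against 629 in RNAi group 3. The filter on the mean over arrays favours probe sets dim on the shared array alone. Without that filter, 1258 were higher and 649 lower in both. Noise at low signal stays open: with a floor of 32 the ratio was 2.53 (interval 1.87 to 3.43, treating probe sets as independent), but the bound of 1.5 set beforehand took no account of scaling, and with median centring added it was 1.56 (1.17 to 2.07). For less flower tissue of every stage on the shared array, the young flower list had a median of 0.01 with an upper bound of 0.42 over 6 members. That bound lay under the 0.5 set beforehand for arguing against it. Such bounds resample genes on the same arrays and leave out the spread between arrays, so a shortfall is not excluded. Over all 16 members, mostly dim, 7 were higher in both and 3 lower. Tapetum genes were close, such as ATA27 at -0.21. Less mature pollen RNA on the shared array may account for the pattern but cannot be told apart from the rest. The 7 kept pollen genes had a median of 0.59 (interval 0.16 to 0.74, percentile 98.02), between the bounds set beforehand of under 0.5 and over 1. They ran from TET11 (55.0 on the shared array against 58.7 and 52.0) to AtVEX1 (30.4 against 98.7 and 68.0). The brightest, NET2D, had 139.8 against 184.7 and 183.7. Over all 19, mostly dim, 14 were higher in both and 2 lower. Silencing of myosin XI-K stayed open for lack of a settled label on 1 array.

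The columns of the GUS control and RNAi group 1 agreed in 22810 of 22810 rows, where other pairs agreed in 56 to 67. Separate arrays that agree by chance are argued against by this count. The values are consistent with 1 array entered under both labels, and which label is right was not tested.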
